A study of Drosophila melanogaster with 2 samples.

How the data were processed

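The samples were 2 ChIP-seq libraries of whole Drosophila melanogaster embryos of mixed sex, 0 to 24 h old, expressing a Pum-eGFP fusion from the pum locus; chromatin was sheared to 200 to 800 bp, per the labels. Both belonged to 1 group, so no groups were compared. The signal of each peak is the authors' own value, deposited in column 7 of each list, and the −log10 of the q-value was likewise deposited by the authors; 97.5% of the optimal peaks on dm6 shared the highest −log10 value, so peaks were ranked by signal. The lists were 1 per replicate, 1 called on both alignments together and 1 cut at the authors' reproducibility threshold, each on dm6 and dm3. The 3970 optimal rows on dm6 were identical to the 3970 strongest rows of the pooled list. The peak caller, its settings and the reproducibility threshold are not given in the sources used here. Read depth is unknown, and intervals for shares cover counting error over peaks or genes only.

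Coordinates are those of dm6, 1-based; the dm3 lists were counted but not annotated, and no coordinates were converted. Gene models came from Ensembl release 115 (BDGP6.54), with 13968 protein-coding genes on 7 arms after transposable elements were set apart. Summits within 250 bp of a stronger one were dropped. Each base had 1 class, in the order promoter (500 bp on either side of a transcript start), 5' UTR, 3' UTR, coding sequence, other exon, intron and intergenic, so a 3' UTR beside another gene's start counted as promoter.

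Shares per arm and class were compared with bases by exact binomial tests, gene lists with other genes by Fisher's exact test, signal by list with 100000 resamples, and motifs by an exact McNemar test against a window 1000 bp from each summit on a randomly drawn side. Protein-coding lists were compared with other protein-coding genes, and non-coding lists with all other annotated genes. All of these tests were two-sided, with Benjamini-Hochberg adjustment within each family and a threshold of 0.05. Replicate agreement was compared with 1000 circular shifts, one-sided. The 30 gene lists, 13 motifs, tests and 42 alternatives were fixed before the data were examined; 8 list symbols were matched to current names through synonyms. A further 9 alternatives and 8 gene lists were added after the data had been seen. The microRNA list used gene symbols, since the annotation has no such gene class.

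Genes were named by a fixed rule: the gene with the nearest start for each of the 20 strongest optimal peaks found among the strongest of both replicates, pum and the known Pum targets, and up to 4 members of each other list with the strongest promoter peaks. Not every gene so chosen is printed for the non-coding lists. Genes sharing a peak with a named gene were also named where this helps to read the value, chosen after their values were seen.

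The code was tested on simulated data. Among 20 sets of 4000 uniformly placed peaks, 0 of 140 class tests and 1 of 140 arm tests passed the threshold. A list of 200 genes, of which a part was given an extra promoter peak, passed and 0 of 20 random lists did. All other peaks in that simulation were placed uniformly, unlike the real peaks. DRE sites written into simulated peaks were called and 0 of 12 other motifs were. For 2 lists of 4000 peaks made to share 60.0%, 60.2% was recovered. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.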

Results

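Chromatin carrying Pumilio (Pum), an RNA-binding translational repressor best known for acting on the 3' UTRs of maternal mRNAs, was profiled by ChIP-seq in Drosophila melanogaster embryos. The embryos expressed a Pum-eGFP fusion and were collected from 0 to 24 h of development, so that all embryonic tissues were mixed. Precipitation was directed at GFP, and 2 biological replicates, numbered 2 and 3, formed the single group. The files hold peak lists with no read counts, so the sequencing depth is unknown. Each replicate had a list of 30000 peaks and background regions on the dm6 build. The authors' optimal list, cut at their threshold of reproducibility between replicates, held the 3970 strongest rows of their pooled list. Membership thus followed pooled signal, and not every listed peak was strong in both replicates. Dropping summits within 250 bp of a stronger summit left 3816 peaks, called optimal peaks here. Control precipitations were not analysed here, so no background measured without the tagged protein stands beside these values.

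Most of the strongest peaks lay at or near transcript starts of genes with varied roles. The highest signal, 2369 in the authors' pooled list, was at a summit on 2L at 481057, in an intron and 1369 bp from the nearest start, that of cbt (FBgn0043364, 2L 476446 to 479688), which encodes a zinc-finger transcription factor. That summit lay outside cbt and inside the span of ush (2L 476220 to 540560). Ugalt (FBgn0024994), a UDP-galactose transporter gene, followed with a promoter summit on X at 2703885 and a signal of 2357, and CG14100 (FBgn0036889) had 2334 at 19590622 on 3L. The gene ph-p, which encodes a Polycomb group protein, had a summit on X at 2137333 with a signal of 1827, and Chro, which encodes a chromodomain protein, had 1733 on 3L at 22878887, within 500 bp of a start of Ssl1 as well. The peak of px on 2R at 22514306 reached 1967. Further members of the 20 strongest reproducible peaks were nearest to CG11050, CG1888, CG13323, Lk6, CenG1A, Art3, PNPase, mRpL41, Tcs5, Pal1, larp, CG32772, CG13921 and Adf1, with signals from 1653 at CG11050 to 1183 at Adf1. The peaks of CenG1A and Art3 were shared with the mitochondrial ribosomal protein genes mRpS23 and mRpS10, whose starts lay within 500 bp of the same summits. The peak assigned to CG13323 was intergenic and 11899 bp from that start. The signal is the authors' own value for a peak and ranks peaks within 1 list.

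Promoters held 51.8% of the optimal summits (1978 of 3816, 95% Wilson interval 50.2 to 53.4%) against 13.3% of the bases, a ratio of 3.893, where a promoter was the 500 bp on either side of an annotated transcript start. Introns held 32.7% of summits (0.836 times their share of bases, adjusted p = 2.84e-16, two-sided exact binomial test) and intergenic sequence 13.3% (0.473 times, adjusted p = 2.70e-106, exact binomial test). The 3' UTRs outside promoters, where Pum is known to bind mRNA, held 27 summits, or 0.708% (0.487 to 1.03%), which was 0.143 times their share of bases (adjusted p = 4.09e-50, exact binomial test). Coding sequence outside promoters and UTRs held 8 summits (0.0163 times its share of bases, adjusted p = 3.44e-210, exact binomial test). Without the order of classes, 53 summits lay in the 3' UTR and 466 in exons of exactly 1 gene, and these counts were not compared with bases. The exact binomial p for promoters was too small for the precision of the computation. Promoter summits lay upstream of the nearest start in 1651 cases and downstream in 323, with a median position of -91 bp (two-sided exact binomial p = 3.89e-214). Rows of the pooled list below the optimal set were also used in place of bases. That list holds peaks and background regions, with −log10 q-values down to 0.0177, so these rows are not all binding sites. Against them the promoter ratio was 2.11, the 3' UTR ratio 0.301 (adjusted p = 6.54e-13, Fisher's exact test) and the intergenic ratio 0.756 (adjusted p = 6.35e-11, Fisher's exact test). Introns did not pass there (adjusted p = 0.254, Fisher's exact test).

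**Figure D1:**
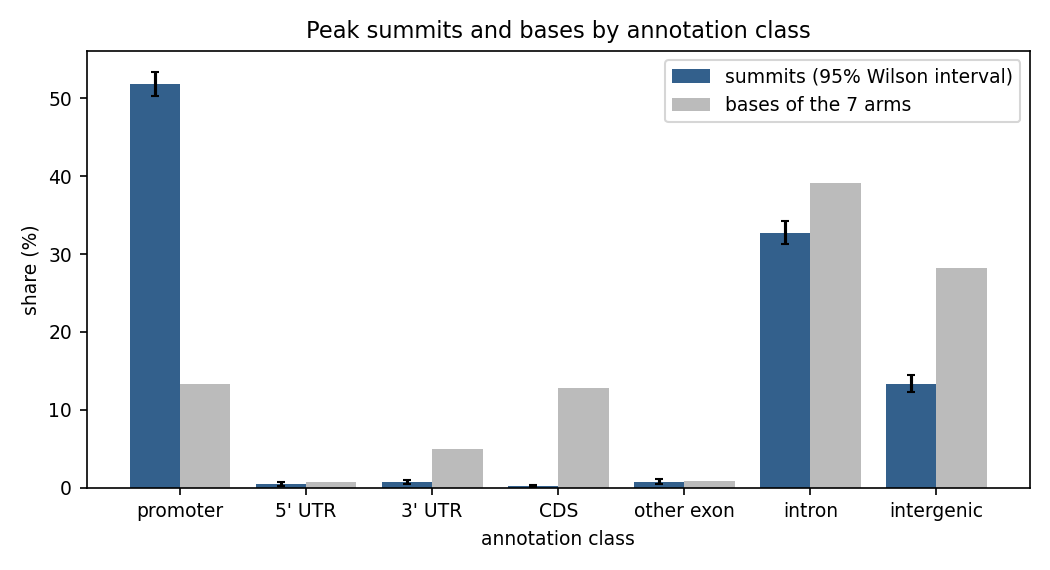
Share of the 3816 optimal summits (blue, with 95% Wilson intervals) and of the bases of 7 chromosome arms (grey) in each annotation class, in percent. Promoters hold 51.8% of summits and 13.3% of bases, and 3' UTRs 0.708% of summits.

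The replicates shared most of their strongest peaks. Of the 3816 strongest peaks of replicate 2, 2607 (68.3%, Wilson interval 66.8 to 69.8%) had a summit within 100 bp among the 3816 strongest of replicate 3. Circular shifts of the summits along each arm gave 0.570% on average and at most 0.970% (one-sided permutation p = 0.001, the smallest that 1000 shifts can give). The peak of Ugalt ranked 1 in replicate 2 and 3 in replicate 3, and that of cbt ranked 3 and 1. Across the 3502 optimal peaks matched in both lists, the signals correlated with Spearman's rho of 0.662 (bootstrap 95% interval 0.638 to 0.683) and Pearson's r of 0.73 on the log2 scale. Peaks are not independent replicates, and the optimal list was cut by the pooled signal of these same libraries. No p is therefore given for the correlation. Of the 3816 optimal peaks, 2641 (69.2%) matched a summit among the 3816 strongest of both replicates. A further 660 did so in replicate 2 only, 453 in replicate 3 only, and 62 (1.62%) in neither. The peaks of dlg1, Cdk1 and E(spl)m7-HLH had no matching summit in 1 replicate, and the peak of N had none in either. Some others matched only outside the 3816 strongest of 1 replicate. Among these, CycB ranked 6664, Antp 5453, crb 6682 and CycE 7528 in replicate 3, and Gli ranked 8309 in replicate 2.

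**Figure D2:**
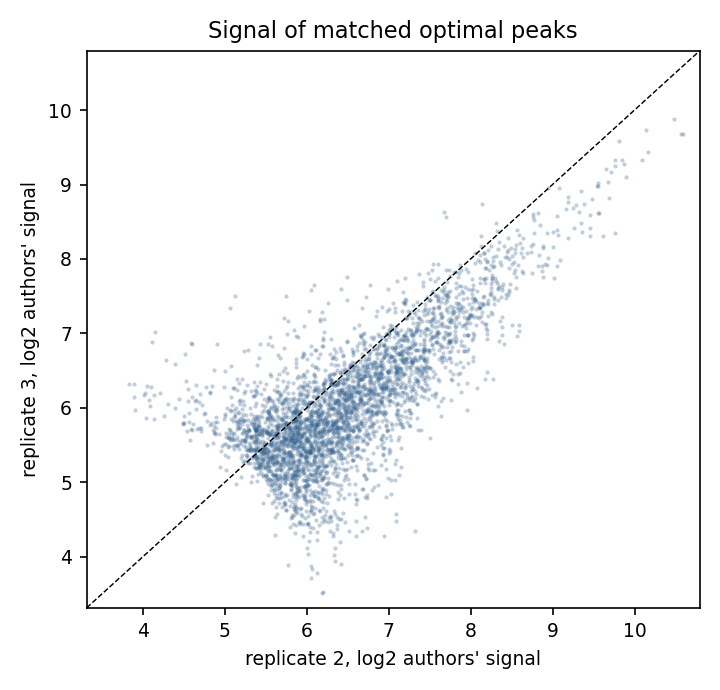
Log2 of the authors' signal in replicate 2 (horizontal) and replicate 3 (vertical) for the 3502 optimal peaks matched within 100 bp in both lists, 1 point per peak, with the dashed line of equal values. The points follow a common trend with Spearman's rho of 0.662.

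Ribosomal protein genes were the gene list with the highest share of promoter peaks. Of 93 such genes, 55 had one (59.1%, Wilson interval 49.0 to 68.6%), against 18.3% of other protein-coding genes, a ratio of 3.22 (adjusted p = 6.24e-17, two-sided Fisher's exact test over 30 lists). RpL34b had a signal of 612, RpL32 601, RpS27 547 and RpS20 488, and each of these summits was also within 500 bp of the start of another gene, such as CG8132 at RpL34b and Nup37 at RpS27. Cofactors of Pum and other maternal RNA regulators had a peak at 11 of 21 genes, a ratio of 2.82 (adjusted p = 0.00152, Fisher's exact test). Among them, tral had a signal of 437, Pop2 306, twin 188 and orb 176; Pop2 and twin encode deadenylase subunits. These 4 summits were also within 500 bp of a start of sti, CG6928, cav and Cdc16, in that order. Chromatin and pioneer factor genes had a peak at 10 of 20, a ratio of 2.69 (adjusted p = 0.00399, Fisher's exact test), with ph-p leading Cp190 at 356, Trl at 329 and brm at 314; the peak of Cp190 was shared with CG4338 and that of brm with Arl1. The cofactor call ended with a promoter window of 250 bp (ratio 2.27, adjusted p = 0.0704, Fisher's exact test), with gene bodies and 1000 bp upstream, matched on length (ratio 1.75, adjusted p = 0.101, permutation test) and with each summit given to the gene with the nearest start (ratio 1.30, adjusted p = 0.658, Fisher's exact test).

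Cuticle protein genes had a promoter peak in 0 of 118 cases, which allows a share of up to 3.15% by the Wilson interval. Odorant and gustatory receptor genes had 1 of 179, the ionotropic receptor gene Ir60e, a ratio of 0.0296 (adjusted p = 5.87e-14, Fisher's exact test), which was 0.0598 with replicate 3 alone and at most 0.120, with the nearest start, in the settings run. Cytochrome P450 genes had 2 of 77, Cyp6u1 with a signal of 410 and Cyp317a1 with 104 (ratio 0.139, adjusted p = 1.50e-04, Fisher's exact test; 0.0880 with a promoter window of 250 bp and 0.211 with the nearest start). The histone list had 1 of 115 genes; that gene, His2Av, encodes a replication-independent variant, and the repeated copies of the other histone genes leave their low share uncertain. The summits of Ir60e, Cyp6u1 and His2Av were also within 500 bp of a start of CG13585, Ufsp1 and ball, in that order. Non-coding classes were compared with all other annotated genes, most of them protein-coding. Of these classes, snRNA genes were not low (6 of 32, ratio 1.23, adjusted p = 0.759, Fisher's exact test). The others were: tRNA genes had 13 of 290, snoRNA genes 11 of 269, microRNA genes 5 of 260 and long non-coding RNA genes 160 of 3289, each with a Fisher's exact test past the threshold. Several of these peaks sat beside protein-coding starts, as at tRNA:Tyr-GTA-1-8 next to CG8036. Gene bodies with 1000 bp upstream, matched on gene length, were scored as well. For short genes such as tRNA and snoRNA genes this is mostly upstream sequence. Neighbouring genes can share 1 summit, while the test treats each gene as independent. In that setting the ratio turned to 3.28 for snoRNA genes (adjusted p = 1.00e-03, permutation test) and to 1.33 for tRNA genes (adjusted p = 0.365, permutation test). The microRNA call ended there (ratio 0.582, adjusted p = 0.163, permutation test), while long non-coding RNA genes passed at 0.772 (adjusted p = 1.00e-03, permutation test). At promoters the ratios were 0.290 for tRNA, 0.264 for snoRNA, 0.124 for microRNA (0.224 with replicate 3 alone) and 0.277 for long non-coding RNA genes. With a window of 1000 bp they were 0.504 for tRNA, 0.270 for microRNA and 0.427 for long non-coding RNA genes. With one of 250 bp they were 0.156 for snoRNA, 0.0643 for microRNA and 0.185 for long non-coding RNA genes. The nearest start gave 0.512 for tRNA and 0.560 for long non-coding RNA genes. All 8 of these values passed Fisher's exact test. The snoRNA call also ended with a promoter window of 1000 bp (ratio 0.890, adjusted p = 0.656, Fisher's exact test).

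Embryonic patterning and tissue lists did not pass the test. Gap genes had a peak at 1 of 12 (cnc, signal 123), segment polarity genes at 1 of 12 (nkd, 120), Hox genes at 1 of 8 (Antp, 83.1), pair-rule genes at 0 of 9 and dorsoventral genes at 2 of 19 (ush, 126, and tin, 123). Notch and neuroblast genes had 3 of 26, led by numb at 322, with E(spl)m7-HLH at 178 and N at 92.8. The neuronal marker elav had a strong promoter peak, with a signal of 560, but was the only 1 of 13 neuron markers with a peak; moody (618) and Gli (86.7) were 2 of 8 glia markers. Muscle markers had 4 of 15 (sls, mys, Mef2 and if), endoderm and fat body markers 2 of 9 (peb and fkh), epidermis and trachea markers 1 of 12 (crb) and heat shock genes 4 of 17 (Hsp27, Hsp83, Hsp26 and Hsc70-4). When each summit was given instead to the gene with the nearest start at any distance, dorsoventral genes passed in the other direction (ratio 2.30, adjusted p = 0.0325, Fisher's exact test) and glia markers passed (ratio 3.41, adjusted p = 0.0178, Fisher's exact test). In that setting gap, pair-rule, segment polarity and Hox genes also had ratios above 1 without passing. Germ cell genes, with 5 of 10 including nanos, tud, piwi and vas, and cell cycle genes, with 7 of 17 including aurA, polo, Cdk1 and CycE, both gave an adjusted p of 0.0604 (Fisher's exact test). The germ cell ratio was 2.69, but 1.61 with replicate 2 alone (adjusted p = 0.720, Fisher's exact test) and 0.934 with the stronger 50% of peaks. The 4 named peaks of germ cell genes were each shared with another gene, such as CG11779 at nanos. The summits of elav, mys, Hsc70-4, aurA and Cdk1 were also near another start. These were starts of lncRNA:enrr, fs(1)h, tefu, CG3281 and mRpS7, in that order. Cell cycle genes passed with replicate 3 alone (ratio 2.87, adjusted p = 0.00355, Fisher's exact test), with a promoter window of 1000 bp (adjusted p = 0.0438, Fisher's exact test) and with the nearest start (adjusted p = 0.0175, Fisher's exact test), but their ratio was 1.26 with replicate 2 alone and 0.863 in peaks of both replicates. Immune effector genes had 0 of 13, chorion and vitelline genes 0 of 11, yolk protein genes 0 of 3 and snRNA genes 6 of 32, among them snRNA:U1:95Ca. Peak signal did not differ past the threshold for any of 10 lists with enough genes (smallest adjusted p = 0.309, two-sided permutation test); at an unadjusted p, snRNA genes alone passed (p = 0.0369, permutation test).

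**Figure D3:**
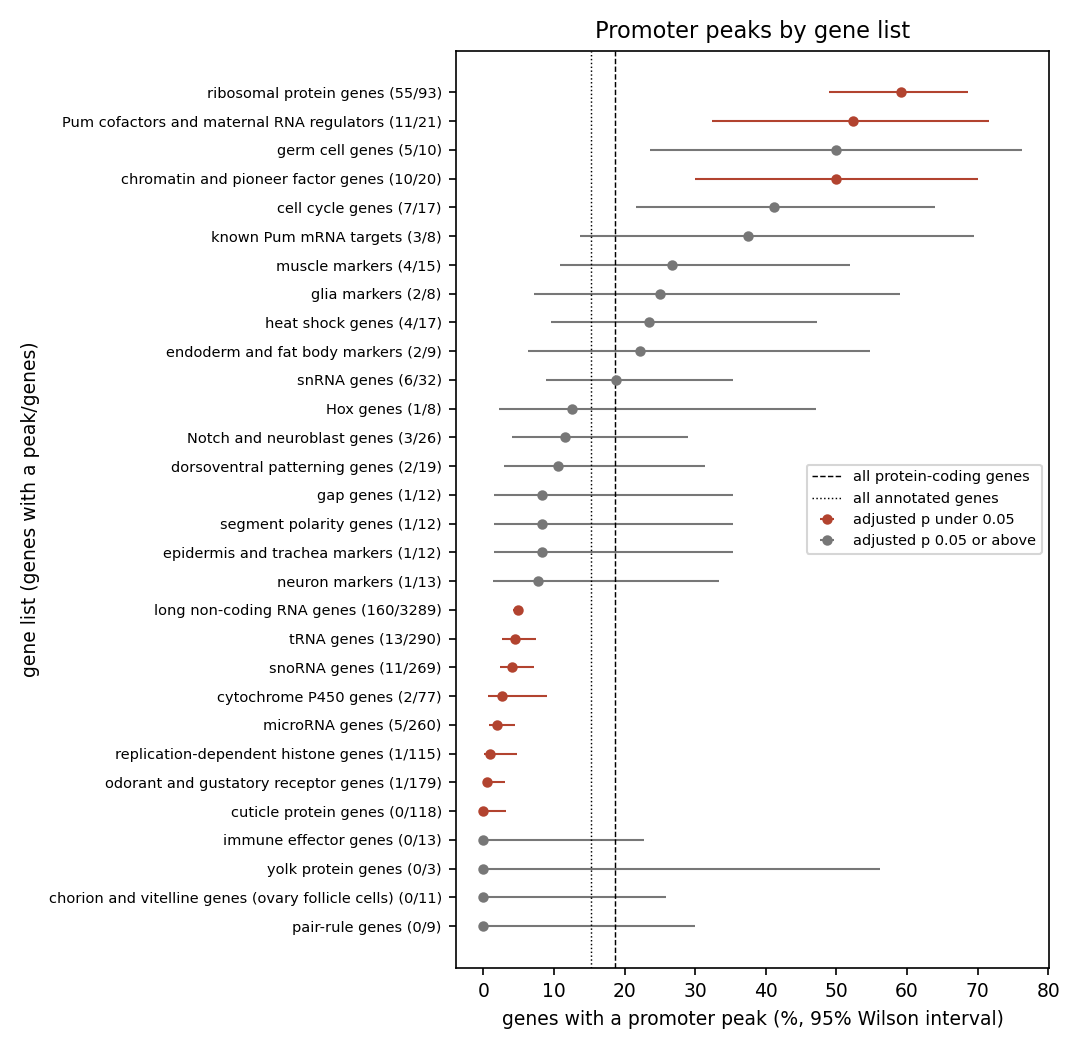
Percent of genes with an optimal summit within 500 bp of a transcript start for each of 30 gene lists, with 95% Wilson intervals, red where Fisher's exact test gave an adjusted p under 0.05. Ribosomal protein genes are highest at 59.1%; dashed and dotted lines mark all protein-coding genes (18.6%) and all annotated genes (15.3%).

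Genes whose mRNAs are known targets of Pum had a promoter peak in 3 of 8 cases, a share that did not differ past the threshold from that of other protein-coding genes (ratio 2.02, adjusted p = 0.347, Fisher's exact test). The ratio turned to 0.677 with replicate 3 alone and to 0.917 in peaks of both replicates, neither of which passed. The anterior determinant bcd had a summit on 3R at 6759662 with a signal of 277, dlg1 one on X at 11390804 with 179, and CycB one on 2R at 22807042 with 81.7. The gap gene hb, whose maternal mRNA is a classical Pum target, had no peak inside the gene, and the nearest summit lay 17863 bp from one of its starts. The sodium channel gene para had 1 peak inside the gene (signal 120) and none at a promoter, while eIF4E1, mei-P26 and Delta had neither.

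The pum gene (FBgn0003165, 3R 9066343 to 9237682, minus strand) contained 6 optimal peaks, all in introns, where uniform placement of the 3816 peaks would give 4.77. The 3816 strongest of replicate 2 held 3 summits in the gene and those of replicate 3 held 5. The strongest had its summit at 9229234, 2394 bp from the nearest pum start, with a signal of 268 in the pooled list, 171 in replicate 2 and 92.9 in replicate 3. The next lay at 9224971 with a signal of 162, and those at 9127094, 9083601, 9220226 and 9230349 had signals from 81.3 to 93.1. No summit was within 500 bp of a start of pum.

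**Figure D4:**
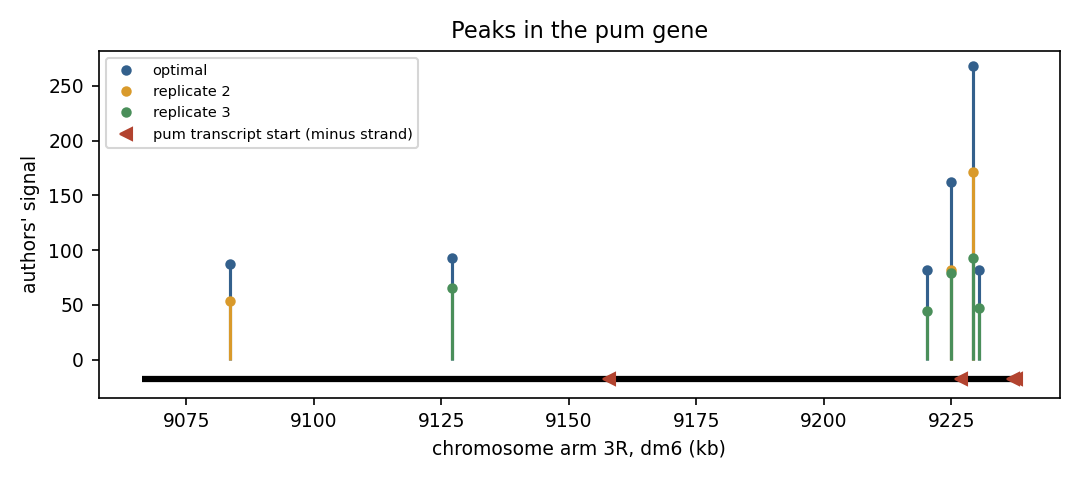
Summits within pum and 2000 bp on either side on 3R (dm6, kb), with the authors' signal as height, for the optimal list and for the 3816 strongest peaks of each replicate; the black bar is the gene and red triangles are its starts. The tallest summit, at 9229234, is present in all 3 lists.

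The sequence recognised by Pum in RNA, TGTANATA read as DNA, was found within 100 bp of 9.17% of the optimal summits and of 8.20% of control windows 1000 bp away, a ratio of 1.12 that did not pass the threshold (adjusted p = 0.207, two-sided exact McNemar test over 13 motifs). GC content was 36.7% in summit windows and 43.0% in control windows, so this control was not matched on base composition. The element passed with windows of 200 bp (ratio 1.13, adjusted p = 0.0484, exact McNemar test) and with control windows 500 bp away (ratio 1.17, adjusted p = 0.0429, exact McNemar test), but against random windows matched on GC content its ratio was 0.992 (adjusted p = 0.937, Fisher's exact test). Near the 466 summits in exons of a single gene, 21 elements were on the sense strand and 19 on the antisense strand (two-sided exact binomial p = 0.875). Near the 53 summits in the 3' UTR of a single gene there were only 2 sense elements and 1 antisense element. That is too few to show a strand preference in 3' UTRs. DRE, the site of the factor Dref, TATCGATA, was more frequent at summits, at 4.51% against 0.655% of control windows (ratio 6.88, adjusted p = 2.02e-27, exact McNemar test). The CTCF core had a ratio of 10 from 50 and 5 windows (adjusted p = 9.26e-10, exact McNemar test), but 5.33 with replicate 3 alone, 6.22 with replicate 2 alone, and from 4.17 to 25 (median 7.14) over 100 other random draws of the side of the control window. Ohler 1 had a ratio of 6.17 (adjusted p = 1.46e-11, exact McNemar test; 9.88 with replicate 3 alone, 3.71 with replicate 2 alone, 3.70 to 12.3 over those draws) and Ohler 6 one of 2.13 (adjusted p = 6.35e-06, exact McNemar test), while the CA repeat was rarer at summits (ratio 0.473, adjusted p = 7.78e-05, exact McNemar test). The calls for DRE, the CTCF core, Ohler 1, Ohler 6 and the CA repeat held in all 100 draws. The CA repeat call ended with windows of 200 bp (ratio 0.878, adjusted p = 0.271, exact McNemar test) and against GC-matched windows (adjusted p = 0.317, Fisher's exact test). The Ohler 6 call ended with the stronger 50% of peaks (adjusted p = 0.0697, exact McNemar test). Of 5 groups of peaks by signal, DRE was at 2.75% of the strongest and 6.16% of the weakest. Ohler 1 was at 0.916% and 3.41% and Ohler 6 at 2.09% and 4.06%, while the CTCF core was at 1.31% and 0.917%. The share of promoter summits was 61.0% in the strongest group and 44.8% in the weakest. These differences by group were not tested. Zelda sites (ratio 0.577, adjusted p = 0.0340, exact McNemar test) and the Initiator (ratio 0.879, adjusted p = 0.0192, exact McNemar test) passed in the planned draw, but in only 9 and 4 of those 100 draws. Zelda also passed with windows of 200 bp (0.685) and control windows 500 bp away (0.536), and the Initiator with windows of 50 bp (0.773) and the stronger 50% of peaks (0.837), each with 1 draw. Both calls ended with either replicate alone (Zelda 0.829 with replicate 3 and 0.688 with replicate 2, the Initiator 1.00 and 0.925), with all rows, in peaks of both replicates and against GC-matched windows. GAGA, E-box, TATA box, GATA and AP-1 motifs did not pass in the planned setting, and AP-1 passed in no other. Over the 100 draws, GAGA passed below 1 in 13 and the E-box in 7. GATA passed above 1 in 7 of them and the Pumilio element in 6. GAGA passed below 1 with windows of 50 bp (ratio 0.456) and control windows 500 bp away (0.654), and above 1 with windows of 200 bp (1.44) and against GC-matched windows (1.81). The E-box passed below 1 in the first pair of those settings (0.739 and 0.840) and above 1 against GC-matched windows (1.502). GATA passed above 1 with control windows 500 bp away (1.26) and against GC-matched windows (1.37). The TATA box passed above 1 with all rows (1.60), with replicate 3 alone (1.71), with control windows 500 bp away (1.72) and in 39 of the 100 draws.

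**Figure D5:**
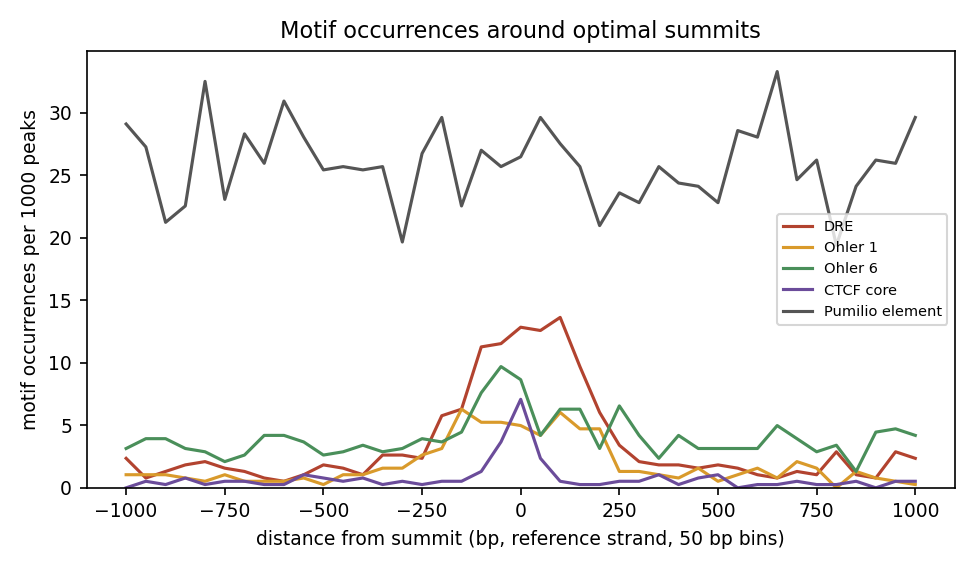
Occurrences of 5 motifs per 1000 optimal peaks, in bins of 50 bp by distance from the summit (bp). DRE, Ohler 1, Ohler 6 and the CTCF core are most frequent near the summit, and the Pumilio element, with 9.17% of summits within 100 bp, shows no rise there.

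Chromosome 4 held 13 optimal peaks, 0.351 times its share of bases (adjusted p = 3.50e-05, two-sided exact binomial test), and Y held 0, though no dm6 list had a peak on Y. The chromosome 4 call ended with the stronger 50% of peaks (ratio 0.540, adjusted p = 0.0976, exact binomial test), and the ratio was 0.216 with replicate 2 alone. The X chromosome held 743 peaks (ratio 1.14, adjusted p = 3.62e-04, exact binomial test) and 2L held 716 (ratio 1.09, adjusted p = 0.0164, exact binomial test), while 2R, 3L and 3R did not pass. The X call ended with replicate 3 alone (ratio 1.04, adjusted p = 0.346, exact binomial test), and with the stronger 50% of peaks (ratio 1.12, adjusted p = 0.0572, exact binomial test). The 2L call ended with either replicate alone, with the stronger 50% and without Y among the arms (ratio 1.07, adjusted p = 0.0878, exact binomial test), where 3L passed (ratio 0.921, adjusted p = 0.0230, exact binomial test). On the older dm3 build the optimal list had 3803 rows, with 19.2% on X against 19.1% on dm6.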

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

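The test of recruitment through nascent mRNA was chosen after its result had been seen; the other tests here were planned before their results, though after the patterns. No biological explanation that the design names was tested, since there is 1 group.

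Peaks on heterochromatic or unplaced sequence of dm3 were outside every comparison of the report and stood out because they were present at all. Replicate 2 had 166 of them among 26275 rows, replicate 3 had 28 among 30000 and the pooled list had 45 among 23478, while the optimal list of 3803 had 0. The replicate 2 list is as long as the pooled list on dm6, but its highest signal of 1549 was near the 1547 of replicate 2 on dm6 and not the 2369 of the pooled list. Of the 166 in replicate 2, 1.81% were among its strongest rows at the size of the optimal list, above the 1% set in advance for weak background and below the 10% set against it, so that explanation stays open. What set the replicates apart was not tested.

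Of 5 groups by signal, the strongest held DRE, Ohler 1, Ohler 6 or the CTCF core at 7.07% and the weakest at 13.6%. All 4 motifs were more frequent at summits than in control windows. Base composition as the whole cause was argued against: in random windows of the same arm and GC content, the lowest ratio among the 4 was 2.34 (Ohler 6, Fisher's exact test). For recruitment at 3' UTRs through Pumilio elements in nascent mRNA, summits in 3' UTRs outside promoters were at 0.143 times their share of bases. Against rows of the pooled list below the optimal set, which include background regions, their ratio was 0.301 (adjusted p = 6.54e-13, Fisher's exact test). Both describe a low share, but the criterion was set with this result known, so it cannot decide the question. Contact away from the element was not tested. Promoter position alone stays open: the 4 motifs together were 1.45 times as frequent at promoter peaks as at promoters without a peak (Fisher's exact p = 1.04e-05), above 1 but short of the 1.5 set in advance. By motif, that ratio was 1.86 for DRE, 3.60 for the CTCF core, 1.08 for Ohler 1 and 1.09 for Ohler 6, and the last pair did not pass Fisher's exact test.

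Promoter peaks at ribosomal protein genes were not accounted for by close neighbours alone: among genes with no other start within 1000 bp, 7 of 21 had a peak, 3.77 times the share of other such genes (Fisher's exact p = 0.00166). Precipitation of open or highly transcribed promoters without the tagged protein was not tested, because control precipitations and expression were not analysed here, and it remains open for this pattern and for the motifs.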

How the results depend on the processing

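The set of peaks found among the strongest of both replicates, the count of arms without Y, the alternatives to the split of X peaks and the other draws of the control side were chosen after seeing the data; all other alternatives were planned. The optimal peak set, replicate agreement and the promoter and 3' UTR shares kept their direction and side of the threshold under every alternative run for them. From 8 to 13 gene lists passed, against 11 as reported, and 0 lists passed on signal in any setting. The Pumilio strand share near exon summits was 50% with a window of 200 bp, against 52.5%, and passed in neither. Causes of the changes below were not tested.

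The correlation was 0.765 over all matched peaks. Arms past the threshold numbered 4, but 1 with the stronger 50% of peaks and 2 to 3 without a replicate. Each count includes Y, whose outcome was fixed because no dm6 list had a peak there, so the 1 was Y alone. There were 3 with Y left out of the arms; 11 motifs passed with control windows 500 bp away. The Pumilio element passed there (1.17) and with a window of 200 bp (1.13), and turned to 0.992 against GC-matched windows.

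Ratios that crossed 1 were these. With GC-matched windows: GAGA 1.81 and E-box 1.502, which passed, AP-1 1.11, Zelda 1.07 and TATA box 0.892. With windows of 200 bp: GAGA 1.44, which passed, and E-box 1.09. With the nearest start: Hox genes 2.73, pair-rule 2.42, dorsoventral 2.30, gap 1.82, segment polarity 1.82, Notch and neuroblast 1.47, epidermis and trachea 1.36, and snRNA 0.974. With gene bodies and 1000 bp upstream, matched on length: snoRNA 3.28, tRNA 1.33, Hox 1.05, dorsoventral 1.00, muscle 0.889, and endoderm and fat body 0.873. With peaks of both replicates: known Pum targets 0.917, glia 0.917, cell cycle 0.863 and AP-1 1.04. With the stronger 50%: germ cell genes 0.934, snRNA genes 0 and arm 3R 0.995. With all rows: arm 2R 1.00 and AP-1 1.01. With a promoter of 250 bp: other exons 1.07, and endoderm and fat body 0.756. Without Y: arm 3R 0.998. X share of promoter peaks against promoter bases without Y: 1.00 with the stronger 50% and 1.02 in peaks of both replicates. Leaving out 1 replicate gave 0.915 to 1.1004 for that share, 0.945 to 1.04 for arm 2R, 0.827 to 1.02 for other exons, 0.677 to 2.69 for known Pum targets, 0.620 to 1.04 for Notch and neuroblast genes, 0.818 to 1.22 for snRNA genes, 0.867 to 1.01 for GAGA and 0.868 to 1.06 for AP-1; log2 signal differences ran from -0.0693 to 0.0911 for Pum cofactors and from -0.0310 to 0.0628 for long non-coding RNAs.

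No paired analysis was possible because there is 1 group. Read depth is unknown, so its effect on weaker peaks could not be measured.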

Other observations

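The gene lists in this part and the split of X peaks by class were chosen after the report's results had been seen; the other tests were set down before their results.

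Of 73 mitochondrial ribosomal protein genes, 32 had a promoter peak, 2.37 times the share of other protein-coding genes (adjusted p = 7.12e-06, Fisher's exact test over 8 added lists). Their strongest were mRpS23 at 1504, mRpS10 at 1476 and mRpL41 at 1393. These summits were also within 500 bp of a start of CenG1A, Art3 and lncRNA:CR44463, in that order. All 3 peaks had been seen among the 20 strongest before the list was added. Other housekeeping lists did not pass: proteasome subunits had 11 of 48 (Rpn5 leading at 395), aminoacyl-tRNA synthetases 7 of 32 (SerRS at 532), translation initiation factors 12 of 44 (eIF6 at 1018), RNA polymerase II subunits 5 of 13 (Polr2H at 520) and spliceosomal proteins 1 of 8 (SmB at 87.4). The peaks named for Rpn5, SerRS, eIF6, Polr2H and SmB were likewise within 500 bp of a start of another gene. Glutathione S-transferase genes had 4 of 35, with GstE13 at 1166, and odorant binding protein genes were low, with 2 of 51 (adjusted p = 0.0140, Fisher's exact test).

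Genes arranged head to head within 500 bp had a promoter peak in 38.6% of 3481 cases, against 26.4% of 595 genes with another kind of neighbouring start that close, and 11.1% of 9892 genes with none. The ratio of the first pair was 1.46 (Fisher's exact p = 6.18e-09), outside what equal shares would give. Head-to-head genes share their upstream side, where 1651 of the promoter summits lay, so 1 summit there can score both genes. How far this raised the ratio was not measured, so it cannot decide on the number of starts per promoter as the cause. A preference for divergent promoters may be involved, as a hypothesis from the same data; genes that share a peak are not independent in this test.

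Of 2196 protein-coding genes on X, 16.6% had a promoter peak, against 19.1% on 2L, 2R, 3L and 3R, a ratio of 0.867 (Fisher's exact p = 0.00505); the ratio was 0.997 with replicate 2 alone, 0.809 with replicate 3 alone (Fisher's exact p = 4.65e-05) and 0.9002 with the stronger 50% of peaks (Fisher's exact p = 0.133). Away from promoters, X held 23.1% of summits against 17.1% of all bases, a ratio of 1.35 (exact binomial p = 8.65e-11). Against bases outside promoters and without Y, the ratio was 1.30 (exact binomial p = 8.88e-09), 1.18 with replicate 3 alone (exact binomial p = 4.41e-04), 1.34 with replicate 2 alone and 1.29 with the stronger 50% of peaks. At promoters it was 0.986 against promoter bases without Y (exact binomial p = 0.808), and 1.1004 with replicate 2 alone (exact binomial p = 0.0513). The call for X as a whole ended with replicate 3 alone and with the stronger 50% of peaks.

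Annotated transposable elements held 9 summits, 0.0398 times their share of bases (exact binomial p = 9.04e-86), which is against placement of peaks over them, though reads from repeats are hard to place and the authors' handling of them is not given in the sources used here. On chromosome 4, replicate 3 listed 201 dm6 rows and replicate 2 listed 42, of which 15 and 8 were among the strongest.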
